A study of Homo sapiens with 9 samples.

How the data were processed

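Total RNA from MDA-MB-231 cells was sequenced 96 h after reverse transfection of siRNA, in 3 groups of 3 libraries: NC, the nontargeting control siRNA, and SKP2-siRNA1 and SKP2-siRNA2, the individual siRNAs that the labels assign to SKP2. Per the labels' protocols, RNA was isolated with the RNeasy mini kit and DNase I treatment. The deposited values are raw read counts per Ensembl gene, 1 file per library. Per the submitters' processing notes, the tools were Trim Galore 0.4.1, FastQC 0.11.2, STAR, HTSeq 0.6.1 and DESeq2 1.16.1, with no statement of the settings, the genome build, the annotation or the strand used in counting. The file contents are integers without normalization. The closing summary lines of each file, which hold reads outside genes or in several genes, were left out of the library totals.

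Each file lists the same 58395 gene identifiers. Of these, 57754 took a symbol from the supplied name table and 521 from GENCODE 29. Coordinates come from GENCODE 29 on GRCh38, matched by gene identifier (58275 found, 120 not found); the build the authors used is not stated. Library totals ranged from 35.5 to 49.9 M gene counts.

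Normalization and tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 16575 genes. Library sizes were scaled by TMM, and the fit was a quasi-likelihood negative binomial model with robust estimation, with group as the only term, over all 9 libraries. Each siRNA was compared with NC, and SKP2-siRNA2 with SKP2-siRNA1, by two-sided quasi-likelihood F tests with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Levels are normalized CPM, given as the mean ± SD of 3 libraries. The SE of a log2 fold change is its size divided by the square root of F. The median SE over the genes was 0.09 for each comparison and the biological coefficient of variation was 0.089.

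A set of 27 gene lists with 859 entries was written down, of which 857 matched a gene in the files; H3C2 and H3C3 did not. The lists were: CDK inhibitors and SKP2 partners, DNA replication and E2F targets, G2/M and mitosis, replication-dependent histones, p53 target genes, ferroptosis and glutathione, NRF2 target genes, unfolded protein response and ER stress, ATF4 and amino acid response, metallothioneins and zinc transport, interferon response, NF-kB and inflammatory cytokines, YAP/TAZ target genes, mesenchymal and matrix genes, epithelial genes, cholesterol synthesis, hypoxia and glycolysis, MYC target genes, FOXO target genes, lysosome and autophagy, oxidative phosphorylation (nuclear), mitochondrial-encoded mRNAs, cytosolic ribosomal proteins, RNA interference machinery, immune cell markers, endothelial cell markers, and luminal breast cancer cell markers. Every list had at least 5 tested members. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the 27 lists. The same test was run with a correlation estimated per list, and fry tested each list by itself. Members past the threshold were also counted after adjustment over the list alone.

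The genes named in the text followed a fixed rule. SKP2, SLC39A7, CDKN1A, CDKN1B and CDKN1C were always named. For changes common to both siRNAs, genes needed a symbol, a mean of at least 2 CPM, adjusted p below the threshold in both comparisons with the same sign, and no overlap between the NC libraries and the knockdown libraries; the 10 largest rises and 10 largest falls were taken, ranked by the smaller of both changes. For changes with 1 siRNA, the 4 largest rises and 4 largest falls were taken among genes of at least 2 CPM that passed against NC for that siRNA and between the siRNAs, and did not pass for the other. For genes moved in opposite directions, the 4 with the largest smaller change were taken. From each list, up to 4 members with the smallest larger adjusted p were available as examples. The groups, lists, tests, naming rule and first set of alternatives were fixed before the data were examined.

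Both siRNAs are compared with the same NC libraries, so 20 data sets with unchanged groups were simulated against shared controls to give the correlation, covariance and overlap that arise with no effect. The tests were checked on simulated counts with 50 genes changed at each of 4 fold sizes. For SKP2-siRNA1 against NC, 26% of the genes changed 1.25-fold, 58% at 1.5-fold, 80% at 2-fold and 98% at 4-fold were recovered, with 17 false calls among 16391 genes. For SKP2-siRNA2 against NC, the shares were 28%, 64%, 80% and 96%, with 13 false calls among 16403 genes. For SKP2-siRNA2 against SKP2-siRNA1, they were 12%, 56%, 84% and 94%, with 5 false calls among 16395 genes. Far more genes passed in the real data, and the adjusted threshold depends on that share. These rates and false calls therefore do not carry over directly to the real comparisons.

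The alternatives were RLE scaling, library size only, no filter on low counts, a filter of 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, a fit on only the groups compared, the replicate number as a block, a threshold of at least 2-fold, each library left out in turn, the estimated correlation, and fry. Offsets for transcript GC content, and the removal of NC replicate 1 together with SKP2-siRNA2 replicate 3, were added after seeing the data. For the closing section, 15964 words of 7 bases were screened in the 3′ UTRs of 12954 genes, with a linear fit across genes on presence of the word, 3′ UTR length and base composition, and 20 shuffles of the genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.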

Results

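RNA was sequenced from MDA-MB-231, a human triple-negative breast cancer cell line, 96 h after reverse transfection of siRNA. The 9 libraries form 3 groups of 3: NC, transfected with a nontargeting siRNA, and SKP2-siRNA1 and SKP2-siRNA2, each transfected with an individual siRNA. The title and the sample labels name SKP2 as the target, whereas the design text names ZIP7 (SLC39A7), a zinc transporter of the endoplasmic reticulum, so both genes are reported. Totals of gene counts for replicates 1 to 3 were 35.5, 45.8 and 48.6 M for NC, 42.5, 39.2 and 49.9 M for SKP2-siRNA1, and 39.6, 43.2 and 46.4 M for SKP2-siRNA2. Of the genes, 16575 were tested, 13135 of them protein-coding. The first and second principal components, with 40.5% and 32.4% of the variance, separated the groups. On the third, with 11.6%, NC replicate 1 and SKP2-siRNA2 replicate 3 lay at -30.3 and -14.6, and NC replicate 3 and SKP2-siRNA2 replicate 1 at 21.2 and 21.7. The labels do not say that the replicates are separate cultures, so the p-values measure the spread between these samples, which may be technical.

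SKP2 is the F-box protein that recruits substrates such as the CDK inhibitor p27 to the SCF ubiquitin ligase. SKP2 (ENSG00000145604, chromosome 5, 36151989 to 36184319) fell with both siRNAs. In NC its level was 57.5, 63.8 and 64.9 CPM in replicates 1 to 3 (62.1 ± 3.99, SD, n = 3), from 2045, 2887 and 3065 counts. With SKP2-siRNA1 it was 3.51, 3.31 and 3.91 CPM (3.58 ± 0.307, SD, n = 3), from 149, 129 and 193 counts. With SKP2-siRNA2 it was 6.09, 5.69 and 6.11 CPM (5.96 ± 0.236, SD, n = 3), from 247, 251 and 285 counts. SKP2 was thus 17.3 times lower with SKP2-siRNA1 (log2 fold change -4.11, SE 0.08, adjusted p = 8.64e-12) and 10.4 times lower with SKP2-siRNA2 (-3.38, SE 0.08, adjusted p = 5.35e-12). Between the siRNAs it was 1.66-fold higher with SKP2-siRNA2 (adjusted p = 6.46e-06). SLC39A7 (ENSG00000112473, chromosome 6, 33200445 to 33204439) passed the threshold with neither siRNA. Its level in replicates 1 to 3 was 339, 352 and 336 CPM in NC and 344, 342 and 343 CPM with SKP2-siRNA1 (adjusted p = 0.936). With SKP2-siRNA2 it was 358, 376 and 359 CPM (log2 fold change 0.09, SE 0.04, adjusted p = 0.0868).

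**Figure D1:**
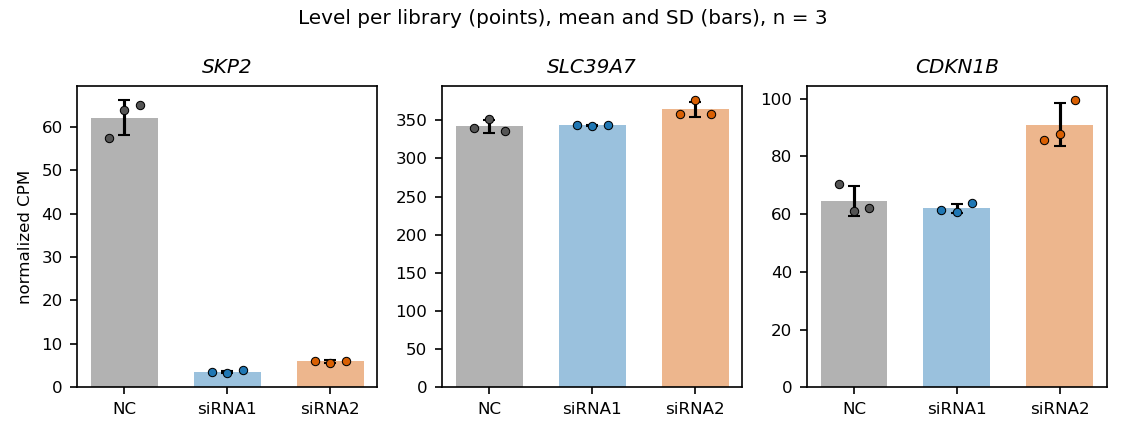
Normalized CPM of SKP2, SLC39A7 and CDKN1B per library (points), with the mean and SD of 3 libraries (bars), in NC and with each SKP2 siRNA. SKP2 was 62.1 CPM in NC and 3.58 and 5.96 CPM with the siRNAs, whereas SLC39A7 stayed between 336 and 376 CPM in every library.

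The SCF-SKP2 substrates p27, p21 and p57 are encoded by CDKN1B, CDKN1A and CDKN1C. The values are RNA levels, and the proteins, on which the ligase acts, were not measured here. CDKN1B (ENSG00000111276, chromosome 12, 12715058 to 12722371) rose 1.41-fold with SKP2-siRNA2, from 64.5 ± 5.16 to 90.9 ± 7.45 CPM (SD, n = 3; log2 fold change 0.50, SE 0.07, adjusted p = 3.81e-05). With SKP2-siRNA1 it was 62.0 ± 1.65 CPM (adjusted p = 0.527), and the siRNAs differed (log2 difference 0.55, adjusted p = 1.44e-05). CDKN1A was 73.9 CPM in NC, 71.6 CPM with SKP2-siRNA1 (adjusted p = 0.755) and 62.9 CPM with SKP2-siRNA2 (log2 fold change -0.23, adjusted p = 0.0784). The second value passed the threshold with DESeq2 (-0.26), without NC replicate 2 (-0.29) and without SKP2-siRNA2 replicate 3 (-0.32). It also passed with GC offsets (-0.35) and without both NC replicate 1 and SKP2-siRNA2 replicate 3 (-0.21), with adjusted p between 0.000159 and 0.208 over all alternatives. CDKN1C was 1.74 CPM in NC, 1.69 CPM with SKP2-siRNA1 (adjusted p = 0.988) and 2.64 CPM with SKP2-siRNA2 (log2 fold change 0.64, adjusted p = 0.144). The last value passed without NC replicate 1 (1.07) and without that library and SKP2-siRNA2 replicate 3 (0.82), with adjusted p between 0.000666 and 0.389 over all alternatives.

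The comparison of SKP2-siRNA1 with NC asks which transcripts change when SKP2 is lowered with the first siRNA. Genes of DNA replication and of mitosis fell together. CDC6, which loads the MCM helicase at replication origins, was 2.44 times lower (145 ± 7.52 to 59.5 ± 1.2 CPM, SD, n = 3), and KIF2C, a mitotic kinesin that depolymerizes microtubules, was 3.28 times lower (226 ± 14.98 to 68.9 ± 2.18 CPM). Among interferon-stimulated and matrix genes, OAS1, a sensor of double-stranded RNA, was 3.26-fold higher (1.11 ± 0.206 to 3.64 ± 0.531 CPM), and LOX, which cross-links collagen, was 2.11-fold higher (67.9 ± 4.52 to 143 ± 1.45 CPM). MMP1, the interstitial collagenase, rose 6.21-fold (20.6 ± 2.06 to 128 ± 5.81 CPM). In all, 7548 of the 16575 genes (45.5%) passed the threshold, 4150 higher and 3398 lower, with a median absolute log2 fold change of 0.43, and 980 of them changed at least 2-fold.

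Of the DNA replication and E2F targets, 45 of 46 tested members fell with SKP2-siRNA1, and 46 when adjusted over the list alone. Their median log2 fold change was -1.06 (camera adjusted p = 1.11e-45; adjusted p = 0.0127 with an estimated correlation). CDC6 (-1.29), GINS1 (-1.27) and MCM7 (-1.02), parts of the replication machinery, were among them. All 46 members of the G2/M and mitosis list fell, also when adjusted over the list alone. Their median was -1.43 (adjusted p = 3.71e-68; adjusted p = 0.0257 with an estimated correlation), and the kinesins KIF2C (-1.71) and KIF23 (-1.53) were examples. Of 16 CDK inhibitors and SKP2 partners, 2 rose and 9 fell, with the same counts adjusted over the list alone. That list's median was -0.21 (adjusted p = 0.000306; adjusted p = 0.11 with an estimated correlation). The fallen members included CCNA2 (-1.31), encoding cyclin A, CDK2 (-0.87), its kinase, and CKS1B (-0.89), the cofactor of SKP2 in p27 recognition.

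The MYC and ATF4 lists were lower with SKP2-siRNA1 at camera's preset correlation. Of 35 MYC target genes, 24 fell, 25 when adjusted over the list alone (median -0.25, adjusted p = 1.18e-05; adjusted p = 0.0656 with an estimated correlation). The ribosome biogenesis factors TCOF1 (-0.83) and NOP58 (-0.61) were among them. Of 33 genes of the ATF4 and amino acid response, 3 rose and 17 fell, 3 and 18 when adjusted over the list alone. Their median was -0.31 (adjusted p = 5.21e-05; adjusted p = 0.11 with an estimated correlation), and SLC7A1, a transporter of cationic amino acids, fell (-1.46).

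Of 44 interferon response genes, 29 rose and 5 fell with SKP2-siRNA1, 30 and 6 when adjusted over the list alone. The median log2 fold change was 0.58 (camera adjusted p = 3.43e-11; adjusted p = 0.121 with an estimated correlation). OAS1 (1.71) and the transcription factor STAT2 (0.43) rose, and GBP1 (-0.65), a guanylate-binding protein, fell. Of 47 mesenchymal and matrix genes, 29 rose and 4 fell, 29 and 5 when adjusted over the list alone. Their median was 0.38 (adjusted p = 2.41e-08; adjusted p = 0.0127 with an estimated correlation). LOX (1.08), fibronectin FN1 (0.80) and TIMP3 (0.59), an inhibitor of metalloproteinases, were among the risen. Of 35 genes of hypoxia and glycolysis, 19 rose and 2 fell, with the same counts adjusted over the list alone. Their median was 0.29 (adjusted p = 3.12e-05; adjusted p = 0.11 with an estimated correlation), with hexokinase HK2 (0.76) and the MYC antagonist MXI1 (0.82). Of 31 genes of NF-kB and inflammatory cytokines, 13 rose and 4 fell, 13 and 5 when adjusted over the list alone, and the cytokine genes IL6 (0.98) and CSF1 (0.61) rose while IL11 (-1.14) fell. That list's median was 0.14 (adjusted p = 0.017; adjusted p = 0.112 with an estimated correlation). Without NC replicate 3 its call was lost (median 0.11, adjusted p = 0.0563, the highest of the leave-one-out fits, which started at 0.00821).

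The NRF2, FOXO and lysosome lists were higher with SKP2-siRNA1 at camera's preset correlation. Of 25 NRF2 target genes, 14 rose, among them the efflux pump gene ABCC3 (0.78), and 1 fell, with the same counts adjusted over the list alone. Their median was 0.18 (adjusted p = 0.000488; adjusted p = 0.11 with an estimated correlation). Of 25 FOXO target genes, 14 rose and 3 fell, 15 and 3 when adjusted over the list alone, with rises of KLHL24 (0.71), which regulates keratin turnover, and catalase CAT (0.48). Their median was 0.35 (adjusted p = 0.000416; adjusted p = 0.14 with an estimated correlation). Of 33 genes of lysosome and autophagy, 15 rose, among them the autophagy receptor SQSTM1 (0.80), and 1 fell, with the same counts adjusted over the list alone. Their median was 0.17 (adjusted p = 0.0019; adjusted p = 0.11 with an estimated correlation).

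Markers of other cell types moved with SKP2-siRNA1 as well. Of 15 luminal markers, 9 rose and 1 fell, with the same counts adjusted over the list alone (median 0.29, adjusted p = 0.00108; adjusted p = 0.11 with an estimated correlation). AGR2, a protein disulfide isomerase, rose by 1.36 on the log2 scale. Of 17 listed immune cell markers only 6 passed the filter on counts and were tested. Of these, 5 rose, also when adjusted over the list alone (median 0.84, adjusted p = 0.0275, and 0.121 with an estimated correlation). The call of ITGAM, 1 of them, was lost in 5 of the leave-one-out fits, with DESeq2 and with the replicate block. CD14, a monocyte antigen, was 1.10 CPM in NC and 2.30 CPM with SKP2-siRNA1. Of 12 listed endothelial markers 6 were tested and 4 rose, also when adjusted over the list alone (median 0.56, adjusted p = 0.0275, and 0.28 with an estimated correlation). KDR, a VEGF receptor, was 3.53 CPM in NC and 7.26 CPM with SKP2-siRNA1. The immune call was lost without NC replicate 1 (adjusted p = 0.0754; 0.0145 to 0.0754 over the left-out libraries). It was also lost with GC offsets (adjusted p = 0.141) and without both NC replicate 1 and SKP2-siRNA2 replicate 3 (0.131; 5.93e-05 to 0.141 over all alternatives). The immune median was 0.97, 0.82 and 0.97 in these fits. The endothelial call was lost without NC replicate 3 (adjusted p = 0.0772; 0.0196 to 0.0772; median 0.475).

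The other 12 lists did not pass with SKP2-siRNA1 by camera, although members moved both ways. By fry 20 lists passed with this siRNA. Among them were the ferroptosis (adjusted p = 0.00258), unfolded protein response (0.0178), zinc (0.00687), YAP/TAZ (0.014) and cholesterol (0.000122) lists. The adjusted p-values below are from camera. Of 20 tested histone genes, whose near-identical copies make single values uncertain, 6 rose and 9 fell, 6 and 11 when adjusted over the list alone (median -0.86, -0.39 with the filter of 1 CPM in at least 3 libraries, adjusted p = 0.561). Of 24 p53 target genes, 9 rose and 6 fell, also over the list alone (median 0.00, adjusted p = 0.841). PHLDA3 (0.88), an inhibitor of AKT, rose and MDM2 (-0.56), the p53 ubiquitin ligase, fell. Counts for the next lists were the same when adjusted over the list alone. Of the ferroptosis and glutathione list 13 rose and 6 fell of 32 (adjusted p = 0.161), and of the zinc list 7 and 3 of 23 (adjusted p = 0.545). YAP/TAZ targets had 10 higher and 8 lower of 26 (adjusted p = 0.545), with a median of 0.05 but a mean of -0.09 and a test direction of lower. Epithelial genes had 11 higher and 6 lower of 26 (adjusted p = 0.463), and cholesterol synthesis 4 and 10 of 31 (adjusted p = 0.101). The last list passed with GC offsets (adjusted p = 0.04; 0.000122 to 0.292 over all alternatives). RNA interference machinery had 3 higher and 6 lower of 13 (adjusted p = 0.569).

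For the unfolded protein response, 8 of 28 genes rose and 4 fell with SKP2-siRNA1, 8 and 5 over the list alone (adjusted p = 0.569). EDEM1, which sorts misfolded glycoproteins, rose by 0.66 on the log2 scale. For oxidative phosphorylation, 5 of 40 rose and 5 fell, 4 and 5 over the list alone (adjusted p = 0.856). Of 13 mitochondrial-encoded mRNAs 2 rose, 1 when adjusted over the list alone (median 0.17, 0.06 without NC replicate 1, adjusted p = 0.264). Of 70 cytosolic ribosomal protein genes 10 fell, 6 when adjusted over the list alone (adjusted p = 0.185). That list passed without SKP2-siRNA2 replicate 1 (adjusted p = 0.0297; 0.0297 to 0.44 over the left-out libraries).

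The comparison of SKP2-siRNA2 with NC asks the same of the second siRNA. Among genes of mitosis and DNA replication, KIF14, a kinesin of the cytokinetic midbody, was 5.94 times lower (154 ± 9.03 to 26.0 ± 1.23 CPM, SD, n = 3), and CDC6 was 2.01 times lower. Among genes of hypoxia and glycolysis, BNIP3, a mitophagy receptor, was 2.50-fold higher (130 ± 2.80 to 326 ± 7.25 CPM), and HK2 was 1.91-fold higher. Among inflammatory genes, IL6 was 2.47 times lower (199 ± 11.2 to 80.6 ± 6.37 CPM), and BIRC3, an inhibitor of apoptosis in TNF receptor signalling, was 4.27 times lower (348 ± 33.2 to 81.5 ± 1.37 CPM). LAMP1, a major lysosomal membrane protein, was 9.32 times lower. In all, 8181 genes (49.4%) passed the threshold, 4184 higher and 3997 lower, with a median absolute log2 fold change of 0.46, and 1137 of them changed at least 2-fold.

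With SKP2-siRNA2, 6 lists passed with camera's preset correlation, and each was lost with an estimated correlation. Of 46 DNA replication and E2F targets, 40 fell, also when adjusted over the list alone, with GINS1 (-1.31) and MCM7 (-0.79). Their median log2 fold change was -0.55 (adjusted p = 1.52e-16; adjusted p = 0.062 with an estimated correlation). Of 46 G2/M and mitosis genes, 45 fell, 46 when adjusted over the list alone, with KIF2C (-1.36) and CCNA2 (-1.05). Their median was -0.99 (adjusted p = 4.99e-41; adjusted p = 0.0667 with an estimated correlation). Of 35 genes of hypoxia and glycolysis, 30 rose and 2 fell, also over the list alone (median 0.47, adjusted p = 1.59e-11; adjusted p = 0.062 with an estimated correlation). Of 31 genes of NF-kB and inflammatory cytokines, 5 rose and 16 fell, 6 and 16 when adjusted over the list alone. Their median was -0.33 (adjusted p = 0.000537; adjusted p = 0.062 with an estimated correlation). IL6 (-1.30) and IL11 (-1.92) fell, and CSF1 (1.11), the macrophage growth factor gene, rose. Of 35 MYC target genes, 2 rose and 20 fell, among them NOP56 (-0.50), 3 and 21 when adjusted over the list alone (median -0.20, adjusted p = 0.00251; adjusted p = 0.184 with an estimated correlation). Of 70 cytosolic ribosomal protein genes, 1 rose and 22 fell, and 19 fell over the list alone. Their median was -0.10 (adjusted p = 0.0076; adjusted p = 0.802 with an estimated correlation), and RPL15 (-1.05) was among them. The ribosomal median was -0.17 both without NC replicate 1 and without SKP2-siRNA2 replicate 1.

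The other 21 lists did not pass with SKP2-siRNA2 by camera, while fry called 20 lists, among them the interferon response (adjusted p = 0.0206). Of 44 interferon response genes 4 rose and 20 fell, also when adjusted over the list alone (median log2 fold change -0.18, adjusted p = 0.122). That list passed without SKP2-siRNA2 replicate 1 (adjusted p = 0.0116; 0.0116 to 0.25 over the left-out libraries). Of 13 mitochondrial-encoded mRNAs 1 rose and 7 fell, also over the list alone, with MT-CO1 at -0.50 (median -0.28, adjusted p = 0.0979). They passed without NC replicate 1 (adjusted p = 0.0349) and without SKP2-siRNA2 replicate 1 (0.0133; 0.0133 to 0.234 over the left-out libraries). Of 6 tested immune cell markers 5 rose, also over the list alone (median 0.91, adjusted p = 0.0505). They included CD14 (0.98) and PTPRC (1.02, from 0.419 to 0.85 CPM), the leukocyte antigen CD45. The immune list passed without SKP2-siRNA1 replicate 1, 2 or 3 (adjusted p = 0.0299, 0.028 and 0.0333). Without SKP2-siRNA2 replicate 1 or 2 it passed too (0.0247 and 0.0437, with 0.0247 to 0.11 over the left-out libraries). It also passed with the replicate block (adjusted p = 0.0249) and with RLE scaling (0.0404, with 5.79e-05 to 0.229 over all alternatives). Of 6 endothelial markers 3 rose, also over the list alone, with KDR at 0.43 (adjusted p = 0.17). Of 15 luminal markers 4 rose and 3 fell, also over the list alone (adjusted p = 0.251); AGR2 (1.45) rose and MLPH (-0.82), a melanosome transport adaptor, fell.

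For these lists too, counts with SKP2-siRNA2 were the same when adjusted over the list alone. CDK inhibitors and SKP2 partners had 3 higher and 9 lower of 16 (adjusted p = 0.0922), with CDK2 at -0.50, and histones 4 and 11 of 20 (adjusted p = 0.328). The ferroptosis list had 11 higher and 9 lower of 32 (adjusted p = 0.753), and the unfolded protein response 4 and 8 of 28 (adjusted p = 0.835). Zinc genes had 5 higher and 10 lower of 23 (adjusted p = 0.122), and YAP/TAZ targets 7 and 11 of 26 (adjusted p = 0.313). Cholesterol synthesis had 11 higher and 9 lower of 31 (adjusted p = 0.904), and FOXO targets 12 and 9 of 25 (adjusted p = 0.69), with KLHL24 at -0.46. Lysosome genes had 15 higher and 6 lower of 33 (adjusted p = 0.77), with SQSTM1 at 0.44.

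In the remaining lists with SKP2-siRNA2, adjustment over the list alone moved the counts. Of 24 p53 target genes 6 rose and 9 fell, 6 and 10 over the list alone (adjusted p = 0.537), and PHLDA3 rose (1.00). Of 25 NRF2 targets 10 rose and 6 fell, 11 and 6 over the list alone (adjusted p = 0.69), and TXNRD1, thioredoxin reductase, fell (-0.75). Of 33 ATF4 genes 7 rose and 17 fell, 10 and 18 over the list alone (adjusted p = 0.251), and CEBPG, a partner of ATF4, fell (-0.97). Of 47 mesenchymal genes 12 rose and 15 fell, 13 and 16 over the list alone (adjusted p = 0.69), and FN1 fell (-0.61). Of 26 epithelial genes 7 rose and 8 fell, 7 and 9 over the list alone (adjusted p = 0.904). Of 40 oxidative phosphorylation genes 4 rose and 5 fell, 3 and 5 over the list alone (adjusted p = 0.904). Of 13 RNA interference genes 2 rose and 7 fell, 2 and 8 over the list alone (adjusted p = 0.0979). With SKP2-siRNA2, the median was -0.13, the mean 0.03 and the test direction lower for p53 targets, and 0.03, -0.05 and lower for ferroptosis. They were -0.01, 0.01 and lower for the unfolded protein response, and 0.13, -0.06 and higher for lysosome. For oxidative phosphorylation the median was 0.00, the mean just below 0 and the test direction lower.

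**Figure D2:**
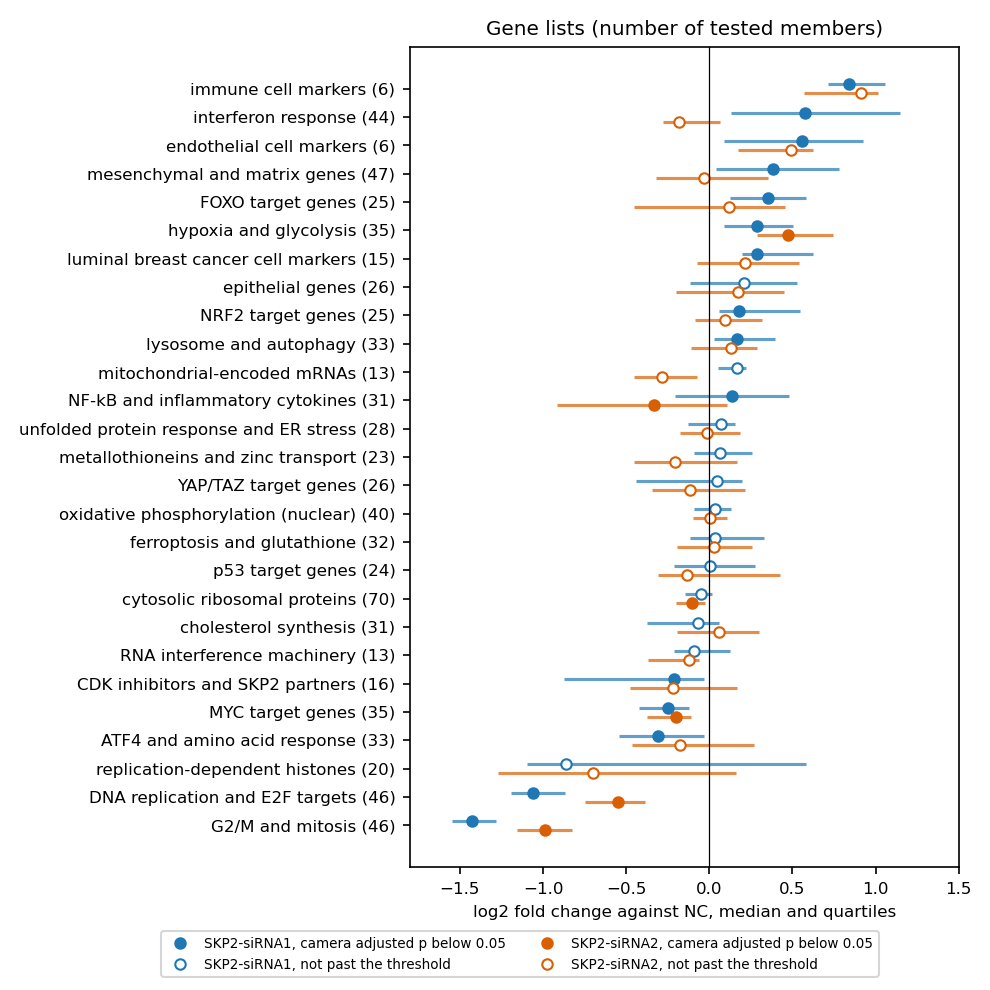
Median (points) and quartiles (lines) of the log2 fold change against NC of each of the 27 gene lists, for SKP2-siRNA1 (blue) and SKP2-siRNA2 (orange), with filled points for a camera adjusted p below 0.05. The G2/M list had the lowest medians, -1.43 and -0.99, and the interferon list had medians on both sides of 0, at 0.58 and -0.18.

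The overlap of both siRNAs asks which changes are found with each of them. DEPDC1B, a cell cycle regulator, was 4.46 and 4.60 times lower with SKP2-siRNA1 and SKP2-siRNA2 (53.3 ± 3.28 to 11.97 ± 1.38 and 11.6 ± 0.697 CPM, SD, n = 3). ANLN, the actin-binding scaffold anillin of the cleavage furrow, was 3.11 and 3.35 times lower (600 ± 45.5 to 193 ± 6.43 and 179 ± 3.52 CPM). NDRG1, a stress-responsive gene induced by hypoxia, rose 3.15-fold and 2.89-fold (134 ± 5.05 to 422 ± 9.80 and 387 ± 5.00 CPM). ESR2, encoding estrogen receptor beta, and PRLR, the prolactin receptor, rose from below 1 CPM: ESR2 7.40-fold and 3.95-fold, PRLR 3.66-fold and 7.64-fold. DEPDC1B had adjusted p = 6.36e-10 and 4.71e-10 (SE 0.09), and NDRG1 3.62e-11 and 4.42e-11 (SE 0.04).

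The other fallen genes that met the naming rule are given with log2 fold changes for SKP2-siRNA1 and SKP2-siRNA2. They were NEK2 (-1.67 and -1.97), a centrosomal kinase, KIF14 (-1.69 and -2.57) and KIF23 (-1.53 and -1.71), kinesins of cytokinesis, PIF1 (-2.07 and -1.74), a DNA helicase, and SHCBP1 (-1.81 and -1.50). FAM72A (-1.68 and -1.51) and FAM72B (-1.86 and -1.79) are near-identical paralogs whose reads can be shared, so that single values are uncertain. Words of 7 bases that are associated with lower levels with SKP2-siRNA2, TGGTGTT or ACCTTTA, occur in the 3′ UTRs of DEPDC1B, KIF14, NEK2, ANLN and SHCBP1. AAGTGAT, the word associated with SKP2-siRNA1, occurs in that of ANLN, and PIF1, KIF23 and the FAM72 genes hold none of these words. Risen genes taken by the naming rule hold them too: ESR2 and RAB3B hold AAGTGAT and TGGTGTT, SAMD5 TGGTGTT, PRLR ACCTTTA and GOLGA7B AAGTGAT. Of the list members given as lower with SKP2-siRNA1, CDC6, GINS1, NOP58 and MDM2 hold AAGTGAT, and KIF2C, MCM7, CCNA2, CDK2, CKS1B, TCOF1, SLC7A1, GBP1 and IL11 do not. Of those given as lower with SKP2-siRNA2, GINS1, RPL15, TXNRD1, CEBPG, MLPH and KLHL24 hold TGGTGTT or ACCTTTA, and KIF2C, CDC6, MCM7, CCNA2, CDK2, IL6, IL11, NOP56 and FN1 hold neither.

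The risen genes were AK5 (2.11 and 2.08), an adenylate kinase, RAB3B (2.05 and 1.45), a GTPase of vesicle secretion, GOLGA7B (1.81 and 2.36) and SAMD5 (1.72 and 1.47). TRPV2 (1.58 and 1.59), a cation channel, SHC4 (1.56 and 1.56), an adaptor of receptor tyrosine kinases, and CST7 (1.54 and 1.66), a cysteine protease inhibitor, rose as well. For the genes taken by the naming rule in the same direction with both siRNAs, adjusted p was at most 0.000153 in each comparison.

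Both siRNAs changed 3914 genes in the same direction (23.6% of those tested), 2092 higher and 1822 lower, against 1048 and 819 expected for independent lists. Of these, 286 changed at least 2-fold with both. Of the 5014 genes past the threshold with both siRNAs, 78.1% moved in the same direction and 1100 in opposite directions. Across genes, the log2 fold changes of both siRNAs had a Pearson r of 0.441 and a covariance of 0.123. Unchanged groups simulated against shared controls gave an r of 0.509 (0.48 to 0.522), a covariance of 0.0203 (0.0188 to 0.0216) and at most 1 gene called in both. That count is low by construction, since adjustment leaves few calls where no gene changes. At an unadjusted p under 0.05 by both F tests with the same sign, 4498 genes passed, against a mean of 151.2 in the simulations. The simulated genes varied independently of each other. The observed covariance exceeded the simulated one by 0.103. Over all genes, 64.1% had the same sign with both siRNAs, against 66.9% in the simulated unchanged groups. Genes are not independent replicates, and the controls were not split, since 3 NC libraries leave 1 part with a single library, so part of the excess overlap may come from the shared controls.

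**Figure D3:**
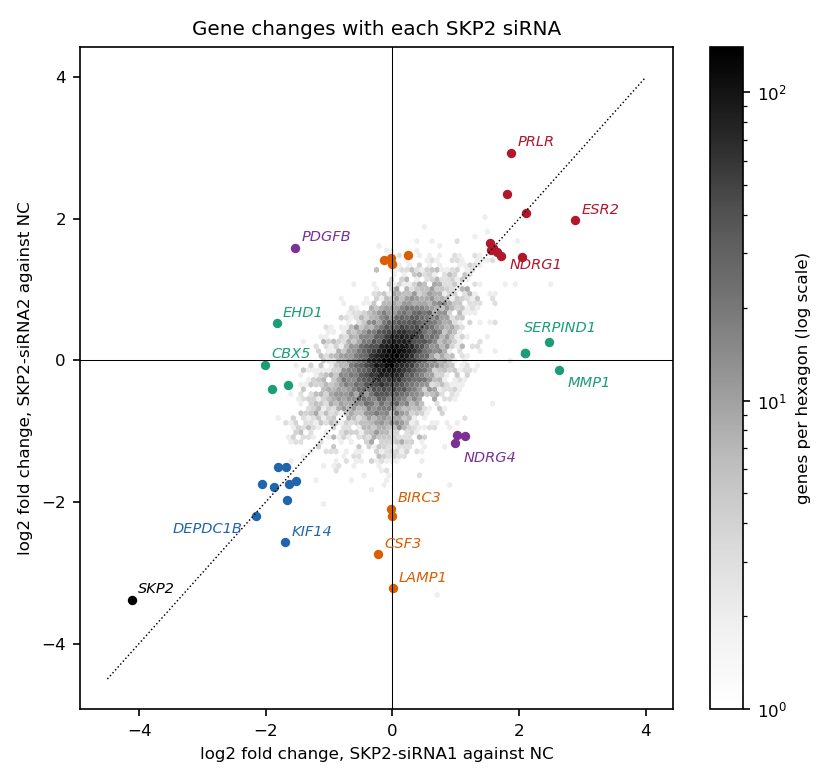
Log2 fold change against NC with SKP2-siRNA1 (horizontal) and SKP2-siRNA2 (vertical) for the 16575 genes tested (grey hexagons, log scale of gene number), with equality dotted and genes of the naming rule coloured: SKP2 black, higher with both red, lower with both blue, SKP2-siRNA1 alone green, SKP2-siRNA2 alone orange, opposite directions purple. LAMP1 lies at 0.01 and -3.22, and MMP1 at 2.63 and -0.14.

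The direct comparison of SKP2-siRNA2 with SKP2-siRNA1 asks where the siRNAs differ. LAMP1 was 9.32 times lower with SKP2-siRNA2 than in NC (212 ± 2.56 to 22.7 ± 1.59 CPM, SD, n = 3) and was 213 ± 1.44 CPM with SKP2-siRNA1 (log2 difference -3.23, adjusted p = 7.71e-13). MMP1 was 128 CPM with SKP2-siRNA1 and 18.7 CPM with SKP2-siRNA2 (log2 difference -2.77, adjusted p = 1.98e-11). TNFSF15, a TNF family cytokine gene, rose 4.27-fold with SKP2-siRNA1 (106 ± 5.11 to 452 ± 13.5 CPM) and was 113 ± 9.39 CPM with SKP2-siRNA2. CBX5, encoding the heterochromatin protein HP1 alpha, was 4.03 times lower with SKP2-siRNA1 (295 ± 21.4 to 73.2 ± 1.67 CPM) and was 283 ± 10.7 CPM with SKP2-siRNA2. In all, 8365 genes (50.5%) differed between the siRNAs, 4175 higher and 4190 lower with SKP2-siRNA2, and 1153 of them at least 2-fold, 426 higher and 727 lower.

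Genes that passed against NC for 1 siRNA only, and also between the siRNAs, numbered 1956 for SKP2-siRNA1 and 2463 for SKP2-siRNA2. With SKP2-siRNA1 the named risen genes were MMP1 (log2 fold change 2.63), SERPIND1 (2.48), encoding heparin cofactor II, MUC5AC (2.10), a secreted mucin, and TNFSF15 (2.10). The fallen ones were CBX5 (-2.01), EHD1 (-1.83), an endocytic recycling ATPase, PKMYT1 (-1.90), the kinase that inhibits CDK1, and CDT1 (-1.64), a replication licensing factor. With SKP2-siRNA2 the named fallen genes were LAMP1 (-3.22), CSF3 (-2.74), encoding G-CSF, MGAT4A (-2.20), a Golgi glycosyltransferase, and BIRC3 (-2.10). The risen ones were CDC42BPG (1.44), a kinase, PDE7B-AS1 (1.49), ITGB1-DT (1.42) and RPL13AP20 (1.37). The last 3 are antisense, divergent or pseudogene transcripts and uncertain, since the strand of counting is not given. The 3′ UTR of CBX5 holds 4 copies of AAGTGAT and that of EHD1 holds 1. Those of LAMP1, MGAT4A and BIRC3 hold 2, 1 and 1 copies of TGGTGTT. CSF3, PKMYT1 and CDT1 hold none of these words. CBX5 also holds 1 copy each of TGGTGTT and ACCTTTA, with a log2 fold change of -0.06 with SKP2-siRNA2, and LAMP1 holds 1 copy of AAGTGAT, with 0.01 with SKP2-siRNA1. In opposite directions with SKP2-siRNA1 and SKP2-siRNA2 moved PDGFB (-1.53 and 1.59), a growth factor gene, S100P (1.14 and -1.06), a calcium-binding protein gene, RORA (1.01 and -1.05), a nuclear receptor gene, and NDRG4 (0.99 and -1.17). RORA holds 1 copy of TGGTGTT and 4 of ACCTTTA, NDRG4 holds 2 of TGGTGTT, and PDGFB and S100P hold none of these words.

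Some of these calls depended on the libraries or settings used. PKMYT1 and CDT1 varied widely within NC (25.3 ± 14.5 and 27.4 ± 12.99 CPM, SD, n = 3). For SKP2-siRNA1 against NC their adjusted p was 0.0183 and 0.0164. These calls were lost without SKP2-siRNA1 replicate 1, 2 or 3 and with the replicate block (0.0537 to 0.0665 for PKMYT1 and 0.0525 to 0.0572 for CDT1), while the log2 fold changes stayed between -1.96 and -1.83 and between -1.67 and -1.62. With GC offsets both genes passed as lower with SKP2-siRNA2 as well (-0.66 and -0.60). Their difference between the siRNAs (adjusted p = 0.0406 and 0.0369) was lost without NC replicate 2, SKP2-siRNA1 replicate 1, 2 or 3, or SKP2-siRNA2 replicate 2 or 3, and with the replicate block (0.0588 to 0.122 for PKMYT1 and 0.055 to 0.11 for CDT1). The log2 difference was then 1.15 to 1.57 for PKMYT1 and 0.99 to 1.33 for CDT1. With SKP2-siRNA2, MMP1 passed as lower without NC replicate 1 (log2 fold change -0.21) or SKP2-siRNA2 replicate 1 (-0.20), and SERPIND1 as higher without NC replicate 3 (0.45). Without NC replicate 1, CBX5 passed as lower (-0.12) and EHD1 as higher (0.77) with SKP2-siRNA2, and PDE7B-AS1 as higher (0.32) and BIRC3 as lower (-0.11) with SKP2-siRNA1. Without NC replicate 3, CSF3 passed as lower with SKP2-siRNA1 (-0.35). With GC offsets CSF3 passed likewise (-0.24), and EHD1 passed as higher with SKP2-siRNA2 (0.34).

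Of the gene lists, 11 differed between the siRNAs with camera's preset correlation, and each of these calls held when any 1 of the 9 libraries was left out. The interferon response list was lower with SKP2-siRNA2 than with SKP2-siRNA1, with 1 member higher and 35 lower of 44, 1 and 36 when adjusted over the list alone. The median log2 difference was -0.70 (adjusted p = 3.45e-15; adjusted p = 0.248 with an estimated correlation). OAS1 rose with both siRNAs (1.71 with SKP2-siRNA1 and 1.22 with SKP2-siRNA2, log2 difference -0.48), and STAT2 rose with SKP2-siRNA1 (0.43) and fell with SKP2-siRNA2 (-0.35, log2 difference -0.77). The NF-kB list was lower as well, with 4 higher and 20 lower of 31, 6 and 20 over the list alone. Its median difference was -0.64 (adjusted p = 1.02e-07; adjusted p = 0.0181 with an estimated correlation), and IL6 differed by -2.29. The mesenchymal and matrix list had 4 higher and 28 lower of 47, also over the list alone. Its median difference was -0.40 (adjusted p = 5.3e-08; adjusted p = 0.0181 with an estimated correlation), and FN1 differed by -1.41.

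The DNA replication and G2/M lists were higher with SKP2-siRNA2 than with SKP2-siRNA1, that is, nearer to NC. Of the DNA replication genes 42 were higher and 1 lower of 46, 43 and 1 when adjusted over the list alone. Their median log2 difference was 0.51 (adjusted p = 2.44e-12; adjusted p = 0.103 with an estimated correlation). Of the G2/M genes 39 were higher and 3, including KIF14 (-0.88), were lower of 46, 40 and 3 over the list alone. Their median difference was 0.41 (adjusted p = 8.78e-10; adjusted p = 0.361 with an estimated correlation). Hypoxia and glycolysis genes were higher too, 21 higher and 4 lower of 35, 22 and 5 over the list alone (median 0.25, adjusted p = 0.00279; adjusted p = 0.341 with an estimated correlation), with BNIP3 at 0.86. So were ATF4 genes, 18 higher and 8 lower of 33, 20 and 8 over the list alone (median 0.33, adjusted p = 0.0169; adjusted p = 0.384 with an estimated correlation), with PSPH, a serine synthesis enzyme, at 0.99.

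The mitochondrial-encoded mRNAs were lower with SKP2-siRNA2 than with SKP2-siRNA1, 1 higher and 8 lower of 13, 1 and 9 when adjusted over the list alone (median log2 difference -0.44, adjusted p = 0.00602; adjusted p = 0.584 with an estimated correlation), with MT-CO1 at -0.72. NRF2 targets were lower, 5 higher and 13 lower of 25, also over the list alone (median -0.21, adjusted p = 0.0182; adjusted p = 0.341 with an estimated correlation), with TXNRD1 at -1.04. FOXO targets were lower, 3 higher and 14 lower of 25, 4 and 14 over the list alone (median -0.20, adjusted p = 0.0182; adjusted p = 0.417 with an estimated correlation), with KLHL24 at -1.17. Lysosome genes were lower, 6 higher and 16 lower of 33, 6 and 17 over the list alone (median -0.17, adjusted p = 0.0169; adjusted p = 0.341 with an estimated correlation), with LAMP1 among them. With GC offsets the ATF4 and FOXO calls ended (medians 0.32 and -0.15, adjusted p = 0.0659 for both). Without both NC replicate 1 and SKP2-siRNA2 replicate 3 the ATF4 call ended (median 0.33, adjusted p = 0.0528; 0.00747 to 0.0659 over the alternatives with camera's preset correlation, and 0.000212 by fry).

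**Figure D4:**
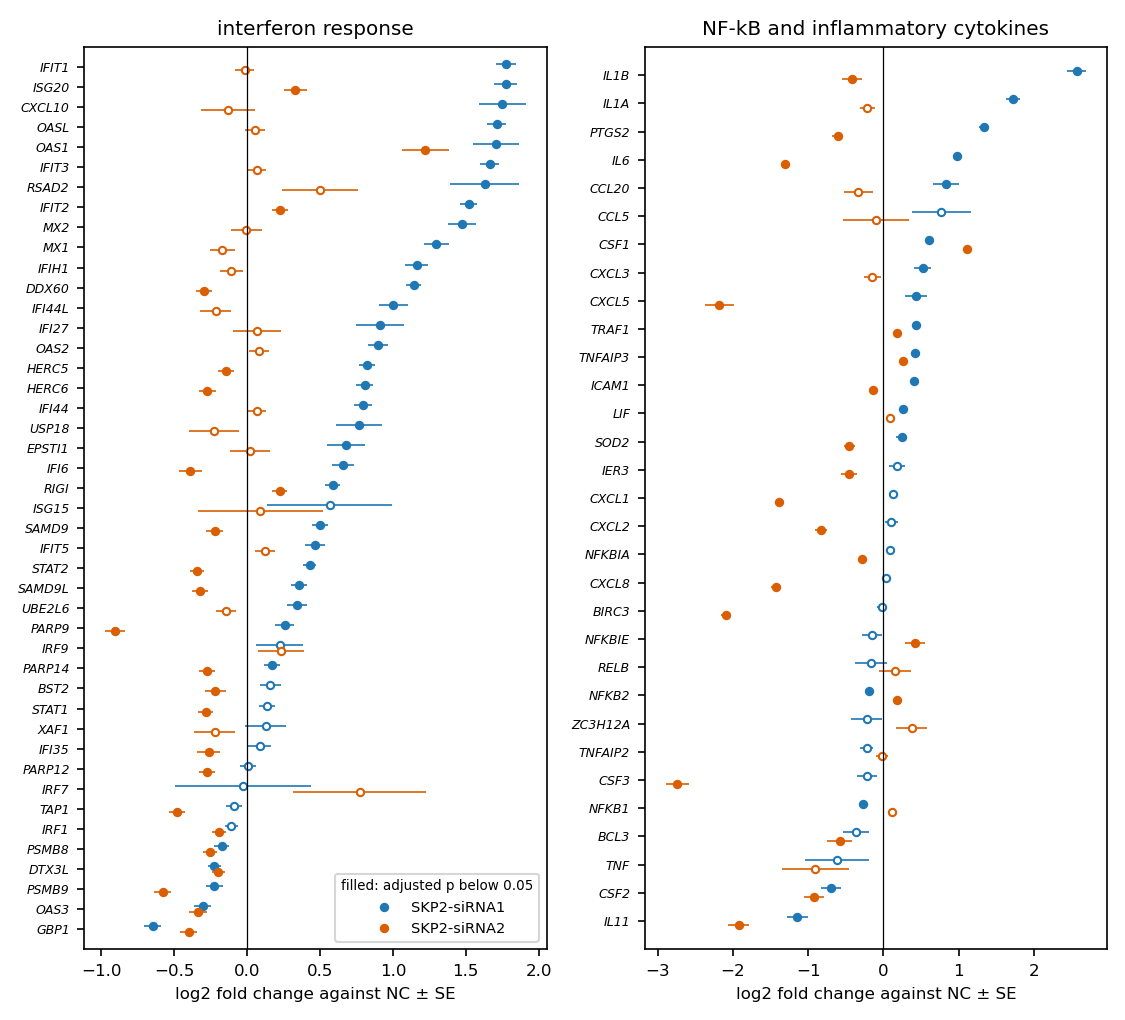
Log2 fold change against NC ± SE (horizontal) of each tested member of the interferon response list (44 genes) and of the list of NF-kB and inflammatory cytokines (31 genes), with SKP2-siRNA1 in blue and SKP2-siRNA2 in orange and filled points for an adjusted p below 0.05. Of the interferon genes 29 rose with SKP2-siRNA1 and 20 fell with SKP2-siRNA2, and IL6 lies at 0.98 and -1.30.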

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

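The tests of a weaker loss of SKP2, and of the words in the values with SKP2-siRNA2, were chosen only after the results were seen.

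The interferon response list moved apart between the siRNAs: its median log2 fold change was 0.58 with SKP2-siRNA1 and -0.18 with SKP2-siRNA2, and the direct comparison gave -0.70 (adjusted p = 0.248 with an estimated correlation). For this difference several technical explanations are argued against as its only source. With any 1 of the 9 libraries left out it stayed between -0.74 and -0.68. Among the 22 members of above-median CPM it was -0.43. Low counts alone thus do not account for it, but members of low CPM add to its size. Among the 21 members whose 3′ UTRs hold no 6-base core of the words of the siRNA strands it was -0.72. With SKP2-siRNA2 the list did not pass against NC by camera (adjusted p = 0.122, and 0.802 with an estimated correlation). Its values were higher in those 21 members: their median was -0.02, against -0.23 in the 23 with a core (two-sided exact rank-sum test, p = 0.023, genes treated as independent). Off-target repression through these words may lower some members, but the test cannot single out the words of SKP2-siRNA2. The cores pool the words of both siRNAs, and 3′ UTR length was not matched. Members without a core were also higher with SKP2-siRNA1 (median 0.80, against 0.58 for all). A weaker loss of SKP2 with SKP2-siRNA2 stays open too, since the median of -0.02 in members without a core (0.80 with SKP2-siRNA1), with 2 higher and 6 lower (two-sided exact binomial test, p = 0.289), does not decide between a lesser rise and a fall. An effect specific to 1 siRNA, such as a response to the siRNA itself or to an off-target gene that acts upstream, was not tested.

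The list of NF-kB and inflammatory cytokines differed between the siRNAs by a median of -0.64 in the direct comparison, with medians of 0.14 and -0.33 against NC. In its 15 members without a core these were -0.67, -0.15 and -0.33, so the rise with SKP2-siRNA1 was not seen there. The mesenchymal and matrix list differed by a median of -0.40, with medians of 0.38 and -0.03 against NC. The mitochondrial-encoded mRNAs differed by a median of -0.44 (adjusted p = 0.584 with an estimated correlation), with medians of 0.17 (0.06 without NC replicate 1) and -0.28 against NC. In addition, 1100 genes passed the threshold in opposite directions with the siRNAs, 727 of them higher with SKP2-siRNA1.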

How the results depend on the processing

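GC offsets and the removal of NC replicate 1 with SKP2-siRNA2 replicate 3 were chosen after seeing the data. SKP2 stayed past the threshold and lower with both siRNAs under each alternative; with 1 library left out it ranged from -4.18 to -4.06 and from -3.44 to -3.35. Leaving out 1 library gave 6429 to 8118 genes for SKP2-siRNA1, 7190 to 9149 for SKP2-siRNA2, 7160 to 9414 between the siRNAs and 3334 to 4477 changed in the same direction by both, with r from 0.417 to 0.497 and 13 to 16 and 6 to 9 lists past the threshold. A threshold of at least 2-fold lowered these counts by its construction to 980, 1137, 1153 and 286. GC offsets gave 8905, 9251, 9369 and 4738 genes, and the removal of both libraries 8755, 8928, 9187 and 4653. DESeq2 gave 6955, 7450, 7661 and 3511 genes, and limma-voom 7582, 8233, 8335 and 3935. Over the alternatives fitted to all genes, 83.7% to 99% of the 3914 genes were called again. On only the groups compared, 44% of the calls for SKP2-siRNA1 and 41.7% of those common to both were higher, against 55% and 53.4%. For SKP2-siRNA2 the share was 51.1%, from 44.5% without SKP2-siRNA2 replicate 1 to 56.9% with library size only. Without that library it was 49.2% for SKP2-siRNA1 and 44% for both. No alternative scaling moved the median of all genes by over 0.1 on the log2 scale. With an estimated correlation camera called 3 lists for SKP2-siRNA1 and 0 for SKP2-siRNA2, where 6 had an unadjusted p under 0.05 and fry called 20; the cause was not tested. By fry the lysosome list turned to lower with SKP2-siRNA2 (adjusted p = 0.00708; 0.603 to 0.991 with 1 library left out). CDKN1C turned to higher with SKP2-siRNA1 after the removal of both libraries (log2 fold change 0.42, adjusted p = 0.0473, the lowest of all alternatives, which reached 0.998); the cause was not tested in either case. Over all alternatives 756 list results kept their direction and side of the threshold, 30 newly passed and 23 no longer passed; for named genes these were 3944, 24 and 35. No pairing by replicate number was seen: deviations of libraries with the same number correlated from -0.498 to 0.055 over 9 pairs, and 1 library correlated best with its own number. The lowest values, -0.498 and -0.455, were those of NC with SKP2-siRNA2 for replicates 1 and 3, which lie apart on the third principal component. That axis could hide a smaller effect shared by a replicate number. With the replicate block, 6818, 7501, 7500 and 3489 genes passed, with 15 and 7 lists. Small effects can be missed: of simulated 1.5-fold changes, 58% were recovered for SKP2-siRNA1. Far fewer genes changed in that simulation than passed in the real data, so the real recovery may differ.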

Other observations

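The tests of the second word with SKP2-siRNA2, of the joint fit for NC and of sequencing depth were chosen only after the results were seen.

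The lists of ferroptosis, zinc and cholesterol synthesis passed with neither siRNA against NC by camera in the main fit, but single members moved. By fry, ferroptosis (adjusted p = 0.00258 and 0.013) and zinc (0.00687 and 2.57e-05) passed with SKP2-siRNA1 and SKP2-siRNA2. Cholesterol synthesis passed by fry with SKP2-siRNA1 alone (0.000122). TFRC, the transferrin receptor that imports iron, fell with both siRNAs and 6.36 times with SKP2-siRNA2, from 626 ± 51.2 to 98.5 ± 1.05 CPM (SD, n = 3). SLC30A1, which exports zinc from the cell, rose with SKP2-siRNA1 (log2 fold change 0.53) and fell with SKP2-siRNA2 (-1.49), while SLC39A9, a zinc importer, fell with both (-1.09 and -0.36). PTGS2, encoding cyclooxygenase-2 and also in the NF-kB list, rose with SKP2-siRNA1 (1.34) and fell with SKP2-siRNA2 (-0.61), as did AKR1C1 (1.49 and -0.85) of the NRF2 list, a ketosteroid reductase with near-identical copies whose value is uncertain. INSIG1, which retains the sterol sensor SCAP, fell with both (-1.04 and -1.64), and so did MSMO1 (-0.48 and -1.01), an enzyme of cholesterol synthesis. The word AAGTGAT occurs in the 3′ UTRs of SLC39A9, PTGS2, AKR1C1, INSIG1 and MSMO1, TGGTGTT in those of TFRC, SLC30A1, SLC39A9 and INSIG1, and ACCTTTA in those of TFRC, PTGS2 and MSMO1.

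The lists of RNA interference, epithelial and YAP/TAZ target genes passed with neither siRNA against NC by camera, and their members moved both ways. By fry, YAP/TAZ targets passed with SKP2-siRNA1 and SKP2-siRNA2 (adjusted p = 0.014 and 0.00369), and RNA interference machinery with SKP2-siRNA2 (0.000686). DICER1, the endonuclease that makes small RNAs, fell with both siRNAs (log2 fold changes -0.58 and -1.36), and so did DGCR8 (-0.35 and -0.37), a microRNA processing factor, whereas TNRC6B (0.59 and -0.41), a silencing factor, moved in opposite directions. Among epithelial genes KRT19 (0.56 and 0.62), a keratin, and ST14 (0.98 and 1.32), the protease matriptase, rose with both and OCLN (-0.68 and -0.50), a tight junction protein, fell with both. AJUBA (-0.44 and 0.44), a LIM protein, and IGFBP3 (0.74 and -0.47), which binds insulin-like growth factors, moved in opposite directions. EDEM1 (0.66 and 0.84), which sorts misfolded glycoproteins, rose with both. AAGTGAT occurs in the 3′ UTRs of DICER1, TNRC6B, OCLN and EDEM1, TGGTGTT in those of TNRC6B and OCLN, and ACCTTTA in those of DICER1, DGCR8, TNRC6B, OCLN, AJUBA and IGFBP3. Of 10 abundant transcripts of blood and endothelial cells, 5 were below 0.1 CPM with SKP2-siRNA1, 4 with SKP2-siRNA2 and 5 in NC, and CD14 and KDR were at 1.10 and 3.53 CPM in NC.

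Other splits of the libraries were compared with the real one. For SKP2-siRNA1 against NC, 1 of the 10 splits gave as many genes: the real one, with 7548 genes, against a highest other of 0 by edgeR, where 404 genes had an unadjusted p under 0.05. For SKP2-siRNA2 against NC it was again 1 of the 10, with 8181 against a highest other of 538, where 2741 genes had an unadjusted p under 0.05. Between the siRNAs it was 1 of the 10, with 8365 against 0 by edgeR, where 213 genes had an unadjusted p under 0.05. For these comparisons the splits are too few for a share under 0.05. For the genes changed in the same direction by both siRNAs, 1 of 100 splits gave as many: the real one, counted among them. It gave 3914 genes against a highest other of 2675. The labels do not say that the libraries are separate cultures, so these splits cannot exclude a chance difference between cultures.

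Among 15964 words of 7 bases, the one most associated with lower levels in 3′ UTRs was AAGTGAT with SKP2-siRNA1 and TGGTGTT with SKP2-siRNA2. Both occur in the coding sequence of SKP2, whose transcripts hold 19.7% of all words. ATTACAA, the word most associated with lower levels in NC, occurs in an untranslated region of SKP2. Occurrence alone thus does not link a word to an siRNA. Of genes with TGGTGTT, 48.4% were lower with SKP2-siRNA2, against 22.4% of those without it. Of genes with AAGTGAT, 36.8% were lower with SKP2-siRNA1, against 19.7%. With the other siRNA, the shares were 35.1% against 24.9% for AAGTGAT and 27.0% against 22.2% for TGGTGTT. These shares do not account for 3′ UTR length. In a joint fit with length and base composition, the log2 coefficients of AAGTGAT were -0.211 with SKP2-siRNA1 and -0.022 with SKP2-siRNA2. For TGGTGTT they were -0.243 with SKP2-siRNA2 and 0.014 with SKP2-siRNA1. Among 4932 genes with no 6-base core of these words or of ACCTTTA, 24.1% changed in the same direction with both siRNAs and 3.5% in opposite directions. Among 8022 genes with a core these shares were 29.2% and 10.9%. Genes with a core also passed more often with SKP2-siRNA1 and SKP2-siRNA2 (56.9% and 61.7%, against 43.5% and 45.3% without). The 3′ UTR length was not matched, so the gap cannot be credited to the words alone. Without a core the G2/M medians were -1.44 and -0.99, and the DNA replication medians -1.08 and -0.41 (-1.06 and -0.55 with all searched members). Some other list medians changed sign. With SKP2-siRNA1 the NF-kB median was -0.15 in the 15 members without a core, against 0.14 in all. With SKP2-siRNA2 the ATF4 median was 0.124, against -0.175 in all. The zinc median with SKP2-siRNA2 was 0.22 in the 6 members without a core, against -0.21 in all.

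The screen took each group's log2 level minus the mean of the other groups. This subtraction raises genes with the other siRNA's word. The strongest word associated with higher levels was TGGTGTT for SKP2-siRNA1 and AAGTGAT for SKP2-siRNA2, so these words are not independent bounds. The z of AAGTGAT was -18.23 (12.29 for the strongest word associated with higher levels, 5.13 in shuffles). That of TGGTGTT was -22.31 (7.24 and 4.96). Both values are consistent with off-target repression through the guide seed of each siRNA, a hypothesis that was not set against the siRNA sequences, since the labels give none. A further word with SKP2-siRNA2, ACCTTTA (z of -15.42), may stem from its other strand. The word's reverse complement lies in exon 3 of SKP2 so that it and TGGTGTT span 17 bases, a placement that 2 of 16384 words have. That share is not a chance rate. ACCTTTA was picked among overlapping words, of which CCTTTAA had a stronger z (-16.42), and the placement was defined after the result. For NC the word ATTACAA had a z of -8.33, below the bound set beforehand by the strongest word associated with higher levels (11.1), but that bound was wrong: its word was AAGTGAT, whose genes are higher in NC by construction, since NC was set against the mean of both siRNAs. With the words of both SKP2 siRNAs in the fit its z was -8.99 (7.14 for the strongest word associated with higher levels). A seed effect of the control siRNA may thus be present, a hypothesis from a fit chosen after the result. In the joint fit, the log2 coefficients of ATTACAA were 0.108 with SKP2-siRNA1 and 0.097 with SKP2-siRNA2. Such an effect would add to the genes called higher with both siRNAs. The 4932 genes without a core were not cleared of ATTACAA, so their shared changes may hold it too.

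NC replicate 1 differed from NC replicate 3, and SKP2-siRNA2 replicate 3 from replicate 1, along a common axis. Transcript GC content followed it across 16555 genes, with a Spearman's rho of 0.53 in NC and 0.42 in SKP2-siRNA2; the second value lies between the bounds of 0.3 and 0.5 set beforehand, so GC content could not be told from other causes as its source. Sequencing depth as the cause is argued against, since the GC-rich library was the shallower in NC (-13.1 M counts) and the deeper in SKP2-siRNA2 (6.8 M). A source such as the library preparation may remain, and no biological explanation was tested. The log2 fold changes followed GC content as well, with a rho of 0.2 for SKP2-siRNA2 against NC. It was 0.181 for SKP2-siRNA2 against SKP2-siRNA1 and 0.006 for SKP2-siRNA1 against NC. Changes with SKP2-siRNA2 and differences between the siRNAs may thus hold a part linked to GC content.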
